A study of Mus musculus with 6 samples.

How the data were processed

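Megakaryocytes of female C57 mice were sorted by flow cytometry straight into Trizol, and biotin-labelled cDNA was made from 250 ng of total RNA and hybridised to an Affymetrix whole-transcript array, per the labels' protocols. The 6 arrays fall into AML (3) and healthy control (3), numbered 1 to 3 in each group by the labels. The authors deposited log2 expression values computed with RMA (background correction, quantile normalization and summary of a row's probes), per the submitters' processing notes, which give no version. The genome build behind the array design is not given in the sources used here. Array medians over genes lay between 5.29 and 5.32 in AML and between 5.16 and 5.24 in control, so that a shift between the groups remained in the deposited values. RMA assumes the same distribution of values on each array, so that the size of a change shared by most genes cannot be read from these values.

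The table holds 72688 rows: 65770 transcript clusters, 5222 negative and 1324 positive controls, 186 unmapped transcripts, 155 ERCC spike-ins, 23 background rows and 8 hybridization or labelling controls. A table pairing rows with the platform's annotation gave 1 gene symbol for 30604 rows, several for 2146 and none for 39938. Rows with several symbols named no gene. Symbols were updated through a RefSeq gene table of the mouse assembly GRCm38.p6, used for names and neighbours only: 22818 matched by gene number, 7476 by symbol and 308 by synonym, 2 did not match, and 1135 symbols changed. Of 429 genes with more than 1 row the row with the highest mean over the 6 arrays was kept, chosen without the groups, which left 30063 genes. Of these, 418 share all their values with another gene. Gp1ba has no row with a single symbol and Hoxa9 is named on rows with several symbols, so these were not analysed here.

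The deposited values were tested as given, with no filter on dim genes, by limma's linear model and moderated test (lmFit and eBayes, without trend), AML against control, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The same fit was run over every row of the table, controls included. The adjusted p of a gene is limma's after that adjustment, and that of a list is limma's camera after adjustment over lists. Tgfb1 also had an exact two-sided permutation test. Before the data were examined, 40 gene lists were fixed from textbook knowledge, covering megakaryocyte identity and function, the MLL-AF9 programme, cell types that the gate could hold, and general processes. The lists share 0 genes. The 39 lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01, beside it with an estimated correlation and with fry. Counts of list members are given over all genes tested and adjusted over the list alone.

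The genes to be named were fixed before the data were examined as well. These included Tgfb1, Pf4, Itga2b, Gp1ba, Gp9, Gata1, Nfe2, Vwf, Hoxa9, Meis1 and Mpo, and the 12 genes with the largest rise and the 12 with the largest fall among named genes past the threshold whose groups did not overlap and whose mean was at or above the median. Added to these were, of each list past the threshold, up to 4 members in its direction with the smallest p and up to 2 in the other, and of each list of another cell type the 2 brightest members. Any other gene named was chosen after its values were seen.

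The alternatives fixed beforehand were the replicate number as a block, a mean-variance trend, array weights, renewed quantile normalization, median centring, cyclic loess, leaving out genes below the lower tertile or below the median level, the mean of a gene's rows, leaving out each array, thresholds with a 1.5-fold or 2-fold minimum, the estimated correlation and fry. Leaving out control rows, counting identical rows once, and leaving out genes at or below the level of olfactory and vomeronasal receptor genes (the 95th percentile of their means, 5.51) were added after seeing the data.

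The fit was tested on data simulated from the mean levels of the 30063 genes. Each gene's SD was drawn at random from the distribution that limma fitted, with noise independent between genes. Array effects, correlation between genes and a shift of all genes were not simulated, so the rates may not hold for the real data. The fit recovered 22 of 50 genes changed 1.5-fold, 39 of 50 changed 2-fold, 47 of 50 changed 2.83-fold and 48 of 50 changed 4-fold, and called 13 unchanged genes. For a simulated list of 21 genes, independent of each other, a shift of 0.2 gave an adjusted p of 2.98e-05 with the preset correlation, 0.571 with an estimated one and 0.157 with fry, while a shift of 0.5 gave 0.0329 with an estimated correlation. R 4.3.3, limma 3.58.1, the data.table package (1.17.8), Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used.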

Results

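Megakaryocytes are the large polyploid marrow cells that release platelets. They were sorted from the bone marrow of mice with acute myeloid leukaemia (AML) driven by the fusion oncogene MLL-AF9 and from the marrow of healthy control mice, by high side scatter, high CD41 (the integrin subunit encoded by Itga2b) and a DNA content of 8N or more. Total RNA of each sort was hybridised to a whole-transcript expression array, with 3 arrays per group, 6 in all. The labels call the arrays of a group biological replicates and give no animal numbers, so p-values measure the spread between these samples. The deposited values are on a log2 scale, ± is the SD over n = 3 arrays of a group, and the number of arrays limits the precision. Differences are AML minus control. The comparison asked how coding and long non-coding transcripts of megakaryocytes differ between leukaemic and healthy marrow.

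In the sorts of AML mice, genes of inflammation, antigen presentation and mature myeloid cells stood lower. With an estimated correlation, however, 0 of the 39 tested gene lists passed. A cluster of cysteine protease inhibitor genes stood far higher. Of 34 genes that define the megakaryocyte, 31 were not past the threshold, and their median level varied between the AML arrays from 8.38 to 9.12. Which cells of the sorts the changed transcripts came from is not known from these data. Il6, the gene of the cytokine interleukin 6, fell from 9.15 ± 0.25 to 5.71 ± 0.32, a 10.8-fold lower level (adjusted p = 3.5e-04), and Il1b, the gene of interleukin 1 beta, fell from 10.53 ± 0.06 to 7.26 ± 0.57, or 9.67-fold (adjusted p = 9.7e-04). Stfa1, a stefin gene encoding an intracellular inhibitor of cysteine proteases, rose from 5.67 ± 0.24 to 11.64 ± 0.23, or 63.0-fold (adjusted p = 4.4e-05). Pf4, the platelet factor 4 gene, stood at 11.98 ± 0.22 against 12.09 ± 0.12 (adjusted p = 0.546).

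Of 30063 genes tested with limma, 3230 passed an adjusted p of 0.05, 1350 higher and 1880 lower in AML. At least 2-fold differences were found in 115 of the higher and 447 of the lower genes. The 3 AML values lay beyond all 3 control values in 12421 genes, or 41.3%. For a single gene chance gives 10%. Genes on the same arrays are not independent and share a shift, so the excess over chance was not measured. The median difference over all genes was +0.11 and became -0.003 after median centring, which left 482 higher and 2269 lower genes. List medians below are therefore given relative to the median over all genes. The count of genes past the threshold was 1938 without AML array 1, 1473 without AML array 2 and 3606 without AML array 3. It was 2931 without control array 1, 967 without control array 2 and 1058 without control array 3. Among genes with a mean at or above the median level, 765 were higher and 1679 lower, and below that level 585 were higher and 201 lower. On AML array 3 the bacterial and phage hybridization controls averaged 11.7, against 10.7 to 11.1 on the other arrays, and the median over 1718 olfactory and vomeronasal receptor genes, a dim family, was 3.81 there against 3.29 to 3.51 elsewhere. The first principal component held 65.2% of the variance and separated the groups, and the second held 18.3%. Correlations across genes, which are not independent replicates, ran from 0.982 to 0.994 within AML, from 0.990 to 0.995 within control and from 0.960 to 0.984 between groups.

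Over all 72688 rows of the array, named or not, 2995 passed, 764 higher and 2231 lower. Of these, 2740 were among 65770 transcript clusters (707 higher, 2033 lower) and 182 among 5222 negative controls (49 higher, 133 lower). Another 67 were among 1324 positive controls (6 higher, 61 lower) and 6 among 186 unmapped transcripts. Of 35331 transcript clusters without a single gene name, 1161 passed, 302 higher and 859 lower. Negative controls passed as well, so a passing row alone was not shown to reflect a transcript. The count over all rows was 1237 without AML array 1, 1241 without AML array 2 and 2607 without AML array 3. It was 3300 without control array 1, 568 without control array 2 and 836 without control array 3. Of 3196 named long non-coding RNA genes, 129 rose and 35 fell, a balance that turned to 42 and 56 under median centring and to 62 and 69 under cyclic loess. Their rises numbered 54 without AML array 1, 43 without AML array 2, 20 without control array 2 and 25 without control array 3, and their falls 14, 18, 11 and 14 without these arrays. Of 19067 protein-coding genes, 812 rose and 1634 fell, and 265 and 1921 did so under median centring. Without AML array 1, AML array 2, control array 2 and control array 3, 361, 236, 121 and 154 of them rose and 1146, 941, 698 and 729 fell.

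The 12 named genes with the largest rise were led by the stefins. Cstdc6 rose at least 52.9-fold, from 5.21 ± 0.19 to 10.94 ± 0.29, and Csta3 rose at least 22.1-fold, from 4.37 ± 0.17 to 8.83 ± 0.23. Csta2, Stfa3, Cstdc4, Cstdc5, Stfa2 and Stfa2l1 rose by between +2.33 and +3.81. The control means of Cstdc6, Csta3, Csta2, Stfa3, Cstdc5 and Stfa2, 4.30 to 5.25, were not shown to be above background, so that their rises are lower bounds. The stefins are close paralogs, so that signal shared between their probes leaves each single value uncertain. Beyond the stefins, Ly6k, a gene of the Ly6 family, rose by +2.51 (a lower bound, from 5.17), Xlr by +2.43, and Eya1, a transcriptional coactivator of the MLL-AF9 programme list, rose 4.63-fold from 5.98 ± 0.07 to 8.19 ± 0.58 (adjusted p = 0.00408).

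The 12 genes with the largest fall held, beside Il6 and Il1b, Gzmb, the gene of the protease granzyme B, which fell 10.1-fold from 10.47 ± 0.16 to 7.13 ± 0.06, and Ighm, the immunoglobulin mu heavy chain gene, which fell by 3.02. Cd209a, a C-type lectin, fell by 2.91 to 4.82, the eosinophil chemokine receptor gene Ccr3 fell by 2.82, and the ficolin B gene Fcnb fell by 2.78. H2-Eb1, an MHC class II chain, fell 6.55-fold from 10.81 ± 0.02 to 8.09 ± 0.21. The chemokine gene Ccl3 fell by 2.62, the steroid synthesis gene Cyp11a1 by 2.59 (or by 1.24 with the mean of its rows), the receptor gene Slamf7 by 2.56 to 5.45 and Fcer1a, of the high-affinity IgE receptor, by 2.54 to 4.50. The falls of Cd209a, Slamf7 and Fcer1a are lower bounds, since their AML means were not shown to be above background.

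**Figure D1:**
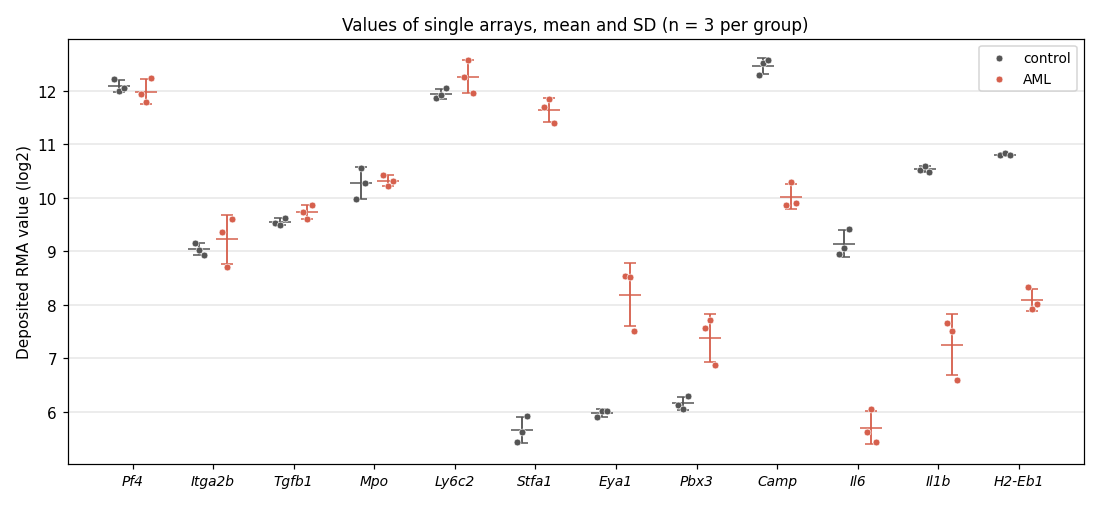
Deposited log2 values of 12 genes on each of the 6 arrays, control in grey and AML in red, with the mean and SD of n = 3 arrays as bars. Pf4, Itga2b, Tgfb1, Mpo and Ly6c2 were not past the adjusted threshold, Stfa1, Eya1 and Pbx3 rose, and Camp, Il6, Il1b and H2-Eb1 fell.

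Few genes that define megakaryocytes and platelets passed the threshold. Their median level was 8.74, 8.38 and 9.12 on AML arrays 1, 2 and 3, against 8.54 to 8.85 on the control arrays. Of 34 measured identity genes, 0 rose and 3 fell, and adjusted over the list alone 1 fell. The 3 were chosen after their values were seen. Plek, the platelet kinase substrate pleckstrin, fell by 0.64, Cd9, a platelet tetraspanin, by 0.41, and F5, coagulation factor V, by 0.59. Their calls were lost without AML array 1, control array 2 or control array 3 (adjusted p 0.0502 to 0.157), and those of Cd9 and F5 also without AML array 2 or control array 1 (adjusted p 0.0659 to 0.0954). F5 also lost its call under quantile normalization (adjusted p = 0.0630) and cyclic loess (adjusted p = 0.0597). Itga2b stood at 9.22 ± 0.46 against 9.04 ± 0.11 (adjusted p = 0.555), Gp9, a subunit of the von Willebrand factor receptor, at 8.05 ± 0.39 against 7.77 ± 0.20 (adjusted p = 0.350), and Vwf at 7.91 ± 0.47 against 7.67 ± 0.12 (adjusted p = 0.438). The list median was +0.01 relative to all genes, its own median and mean were above 0 while the set test pointed down, and the list did not pass (adjusted p = 0.250). Without AML array 3 it passed downward (adjusted p = 0.0019, median -0.07), with 4 genes fallen and 0 risen. Gp1ba was not analysed here.

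Of 19 megakaryocyte transcription factors, 2 rose, also when adjusted over the list alone, and 0 fell. These were chosen after their values were seen. Srf, the serum response factor, rose by +0.45 and Erg, an ETS factor, by +0.53. The call of Srf was lost without control array 2 (adjusted p = 0.0533) and that of Erg without AML array 1, AML array 2 or any single control array (adjusted p 0.0528 to 0.091). Gata1, the master regulator of the lineage, stood at 6.29 ± 0.15 against 6.01 ± 0.08 (adjusted p = 0.110), and Nfe2, which drives platelet release, at 7.88 ± 0.13 against 7.48 ± 0.18 (adjusted p = 0.0674, and under 0.05 in 6 of 17 alternatives, from 0.0127 with array weights to 0.0499, among them leaving out control array 1, 0.0402). Without AML array 3, 4 rose, under quantile normalization and cyclic loess 3 rose, and under median centring, where Srf and Erg lost their calls (adjusted p 0.0560 and 0.0792), 0 rose. The list did not pass (adjusted p = 0.561, relative median -0.01, and the median itself, +0.10, turned below 0 under median centring), but passed upward under quantile normalization (adjusted p = 0.0469) and cyclic loess (adjusted p = 0.0379).

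The machinery of platelet formation and of JAK-STAT signalling held a few lower genes. Of 28 cytoskeletal genes of proplatelets, 4 fell, also when adjusted over the list alone, and 0 rose. The list passed downward (adjusted p = 9.6e-04, relative median -0.18), not with an estimated correlation (adjusted p = 0.240). Rock1, a kinase acting on myosin, fell 1.95-fold from 7.94 ± 0.11 to 6.98 ± 0.05, and the small GTPases Cdc42 and Rhoa and the formin gene Diaph1 fell by 0.44, 0.46 and 0.47. The calls of these last 3 were lost without AML array 2, control array 2 or control array 3 (adjusted p 0.0867 to 0.124), and 1 or more of them without each of the other arrays (adjusted p 0.0525 to 0.0666). Of 20 genes of JAK-STAT signalling and its adaptors, a list fixed beforehand under a narrower name, 4 fell (8 adjusted over the list alone) and 0 rose (adjusted p = 4.4e-06, relative median -0.33, adjusted p = 0.208 with an estimated correlation). The kinase gene Pim1 fell by 0.61, Jak2, a kinase bound to cytokine receptors, by 0.91, the adaptor gene Gab2 by 0.68 and Stat3 by 0.38. The calls of Jak2, Gab2 and Stat3 were lost without AML array 1, AML array 2, control array 2 or control array 3 (adjusted p 0.0565 to 0.143), that of Gab2 also without AML array 3 (adjusted p = 0.0524), and that of Stat3 under quantile normalization (adjusted p = 0.0626) and cyclic loess (adjusted p = 0.0823).

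Secreted factors that act on the marrow niche were lower or not past the threshold. Monocyte and macrophage markers stood lower in the same sorts (relative medians -1.44 and -1.16). Which cells the secreted factor transcripts came from is not known from these data. Of 31 secreted factor genes, 8 fell and 0 rose, and adjusted over the list alone 12 fell and 1 rose. The list passed downward (adjusted p = 2.9e-05, relative median -0.24), not with an estimated correlation (adjusted p = 0.156). After Il6 and Il1b, the examples were Hgf, hepatocyte growth factor, lower by 3.59-fold at 6.82 ± 0.38 against 8.66 ± 0.27, and Cxcl12, the chemokine that retains stem cells in the marrow, which fell by 0.76. Igf1 and Il1a, chosen after their values were seen, fell by 1.29 and 1.15. Tgfb1, the gene of interest fixed beforehand and the source of a signal that keeps blood stem cells quiescent, stood at 9.74 ± 0.13 against 9.55 ± 0.07, a difference of +0.18 (SE 0.09, 95% CI -0.03 to 0.40). Its adjusted p was 0.194 and its exact two-sided permutation p was 0.2, where the smallest that 3 against 3 arrays allow is 0.1.

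Genes of the TGF-beta signalling list stood lower, as did the monocyte and macrophage markers of the same sorts (relative medians -1.44 and -1.16), and which cells these transcripts came from is not known from these data. Of 27 measured, 13 fell and 0 rose (adjusted over the list alone 14 fell and 1 rose), and 8 fell without control array 2 and 8 without control array 3. The list passed (adjusted p = 4.0e-10, relative median -0.46), not with an estimated correlation (adjusted p = 0.0786). Id2, a target of the pathway, fell 2.58-fold from 8.93 ± 0.07 to 7.56 ± 0.08, and Tgif1, a transcriptional corepressor, fell 2.77-fold from 8.16 ± 0.15 to 6.69 ± 0.10. Skil, an inhibitor of SMAD proteins, fell by 1.12 and Tgfbi by 1.74. The receptor gene Tgfbr1 fell by 0.89 and the signal transducer Smad3 by 1.13, both chosen after their values were seen.

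Genes of the MLL-AF9 leukaemia programme moved both ways. Of 15 measured, 6 rose and 2 fell, and adjusted over the list alone 9 rose and 2 fell. These genes beyond Eya1 were chosen after their values were seen. Hoxa6 rose by +1.10, the homeobox gene Pbx3 rose 2.34-fold from 6.16 ± 0.12 to 7.39 ± 0.45, and Hoxa10, Hoxa3 and the cell cycle kinase Cdk6 rose by +0.60, +0.47 and +0.90, while Cpeb2 fell by 1.10 and Lmo4 by 0.39. The call of Pbx3 was lost without control array 2 (adjusted p = 0.0745) or control array 3 (adjusted p = 0.0563), and those of Hoxa10, Hoxa3 and Cdk6 without AML array 1, AML array 2 or any single control array (adjusted p 0.0564 to 0.123). That of Lmo4 was lost without any single AML array, control array 2 or control array 3 (adjusted p 0.0514 to 0.139). The rises numbered 3 without AML array 1, 3 without AML array 2, 3 without control array 1, 2 without control array 2 and 2 without control array 3, and 3 under median centring, where the calls of Hoxa10, Hoxa3 and Cdk6 were lost (adjusted p 0.0718 to 0.101). They numbered 9 without AML array 3. Hoxa3 also lost its call under quantile normalization (adjusted p = 0.0777) and cyclic loess (adjusted p = 0.0734), and Lmo4 under quantile normalization (adjusted p = 0.0600). Meis1, the partner of HOXA proteins, stood at 7.83 ± 0.31 against 7.24 ± 0.10 (adjusted p = 0.0563) and passed upward in 7 of 17 alternatives (adjusted p 0.0048 to 0.0423), the lowest without AML array 3 (difference +0.77), while Hoxa9 was not analysed here. The list did not pass (adjusted p = 0.257, relative median +0.48) but passed upward without AML array 3 (adjusted p = 0.0085) and under cyclic loess (adjusted p = 0.0403).

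Markers of granulocyte-monocyte progenitors, the cells that MLL-AF9 leukaemia resembles, also split. Of 13, 2 rose and 4 fell, and adjusted over the list alone 6 rose and 4 fell. Mpo, the myeloperoxidase gene, stood at 10.32 ± 0.11 against 10.27 ± 0.29 (adjusted p = 0.824), and Elane, neutrophil elastase, at 10.96 ± 0.11 against 10.62 ± 0.17 (adjusted p = 0.0889, or 0.0333 with array weights). The rest, beside Fcnb, were chosen after their values were seen. The protease gene Ctsg rose by +0.95 and the transcription factor Gfi1 by +0.59, and Igsf6 fell by 0.75, the transcription factor Irf8 by 0.66 and Rgcc by 0.57. The calls of Gfi1 and Irf8 were lost without control array 2 or 3 (adjusted p 0.0543 to 0.0659), that of Ctsg without AML array 1, AML array 2 or control array 2 (adjusted p 0.0682 to 0.0915) and under median centring (adjusted p = 0.0556), and that of Rgcc without any single array but AML array 2 (adjusted p 0.0519 to 0.139). The list median was above 0 (+0.17, relative +0.06) while its mean (-0.11) and its test pointed down, and the list did not pass (adjusted p = 0.469).

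Markers of mature myeloid cells stood lower in the AML sorts, with the stefins as the exception. Of 19 neutrophil markers, 13 fell and 3 rose, the 3 being Stfa1, Stfa2 and Stfa3 (adjusted over the list alone, 15 fell and 3 rose; adjusted p = 6.4e-10, relative median -1.10, adjusted p = 0.208 with an estimated correlation). Camp, the cathelicidin gene of neutrophil granules, fell 5.42-fold from 12.46 ± 0.15 to 10.02 ± 0.24, Ltf, lactoferrin, by 2.30, S100a8, a calcium-binding alarmin, by 2.16 and Retnlg by 1.06. Of 18 monocyte markers, 16 fell and 0 rose, over all genes as over the list alone (adjusted p = 1.4e-20, relative median -1.44, adjusted p = 0.0786 with an estimated correlation). Ms4a4c fell 5.50-fold from 8.04 ± 0.17 to 5.58 ± 0.05, the chemokine gene Ccl9 4.38-fold and Clec4a3 4.64-fold. Lyz2, lysozyme, chosen after its values were seen, fell 2.83-fold from 11.03 ± 0.09 to 9.53 ± 0.29. Ly6c2, the marker of inflammatory monocytes, stood at 12.27 ± 0.30 against 11.95 ± 0.10 (adjusted p = 0.187, or 0.0483 without AML array 3 and 0.0357 with array weights). Of 18 macrophage markers, 14 fell and 0 rose, and 18 fell adjusted over the list alone (adjusted p = 4.8e-17, relative median -1.16, adjusted p = 0.156 with an estimated correlation). Cd163, a scavenger receptor, fell by 1.22, Mrc1, the mannose receptor, by 1.95 and Spic, the transcription factor of iron-recycling macrophages, by 1.05. The macrophage count was 9 without AML array 2, 5 without control array 2 and 5 without control array 3.

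Markers of eosinophils, basophils and mast cells stood lower as well. Of 10 eosinophil markers, 7 fell (8 adjusted over the list alone) and 0 rose, and 4 fell without control array 2 and 4 without control array 3 (adjusted p = 2.4e-09, relative median -0.78, adjusted p = 0.156 with an estimated correlation). Beside Ccr3, Il5ra, the interleukin 5 receptor, fell by 1.38. Prg2, the major basic protein gene, stayed among the highest values at 12.30 ± 0.19 against 12.74 ± 0.08 (adjusted p = 0.0468), a call lost without any single array but AML array 3 (adjusted p 0.059 to 0.157). Of 11 basophil and mast cell markers, 5 fell (7 adjusted over the list alone) and 0 rose (adjusted p = 1.1e-07, relative median -1.06, adjusted p = 0.0786 with an estimated correlation). The mast cell protease gene Mcpt8 fell 3.87-fold from 10.48 ± 0.16 to 8.52 ± 0.13, Prss34, a basophil protease, fell 5.25-fold, Ms4a2, the IgE receptor beta chain, fell by 1.14, and Fcer1a is given above. Il6ra, chosen after its values were seen, fell by 0.65, a call lost without AML array 1, AML array 2, control array 2 or control array 3 (adjusted p 0.0834 to 0.12) and under cyclic loess (adjusted p = 0.0562).

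Lymphoid, dendritic, erythroid and endothelial markers were lower by less, and most of the brightest members of these lists were not past the threshold. Of 14 B cell markers, 5 fell and 0 rose (adjusted over the list alone 8 fell and 1 rose; adjusted p = 3.0e-05, relative median -0.42, adjusted p = 0.156 with an estimated correlation), led by Fcrla (fell by 1.21), Ms4a1, which encodes CD20 (fell by 1.19), and the transcription factor Ebf1 (fell by 0.87). The B cell count was 3 without AML array 2, AML array 3, control array 1 or control array 2, but 7 under median centring and 8 under cyclic loess. Of 8 plasma cell markers, 3 fell, also adjusted over the list alone (adjusted p = 0.0102, relative median -0.27, adjusted p = 0.156 with an estimated correlation), Irf4 by 0.97, Prdm1 by 0.96 and Jchain by 2.14. The call of Prdm1 was lost without control array 2 (adjusted p = 0.0503) and that of Jchain without AML array 2, control array 2 or control array 3 (adjusted p 0.078 to 0.104), which left 1 call without control array 2. Of 10 dendritic cell markers, 2 fell (3 adjusted over the list alone; adjusted p = 0.00284, relative median -0.16, adjusted p = 0.225 with an estimated correlation). Itgax, which encodes CD11c, fell by 1.12 and Siglech by 0.65, the latter not without control array 2 (adjusted p = 0.0533). Of 16 erythroid markers, 8 fell (11 adjusted over the list alone) and 0 rose, 5 without AML array 2 and 4 without control array 2 (adjusted p = 2.2e-08, relative median -0.41, adjusted p = 0.136 with an estimated correlation). Rhag fell by 0.80 and Alas2, the first enzyme of heme synthesis in red cells, by 0.82. Of 14 endothelial markers, 6 fell, also adjusted over the list alone, and 0 rose, 1 without AML array 2, 2 without control array 2 and 3 without control array 3 (adjusted p = 4.4e-06, relative median -0.32, adjusted p = 0.208 with an estimated correlation). Stab2, a scavenger receptor of sinusoids, fell by 0.90. Of the brightest members, Vpreb2 (B cell), Tnfrsf13b (plasma cell), Clec9a (dendritic), Epor (erythroid) and Ly6c1 (endothelial) differed by +0.19, +0.21, +0.59, +0.19 and +0.26, and Xbp1 (plasma cell), Aqp1 (erythroid) and Tie1 (endothelial) by -0.04, -0.26 and -0.10, none past the threshold. With array weights Tnfrsf13b and Ly6c1 passed upward (adjusted p = 0.0359 and 0.0480), and without AML array 3 Aqp1 passed downward (adjusted p = 0.0437).

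T and NK cell, stem cell and stromal markers did not pass as lists (adjusted p = 0.698, 0.328 and 0.320). Their medians were +0.09, +0.03 and +0.07, or -0.02, -0.08 and -0.04 relative to all genes, and turned below 0 under quantile normalization, median centring and cyclic loess, while the tests pointed down. The members named for their calls were chosen after their values were seen. Of 16 T and NK cell genes, Ncr1 rose by +0.34 and the NK receptor gene Klrd1 fell by 0.97 (adjusted over the list alone, 1 rose and 3 fell). Of 14 stem cell genes, Cd34 rose by +0.66 and Tek fell by 0.38, with the same counts adjusted over the list alone. Of 16 stromal genes, Pdgfrb rose by +0.40 and Adipoq, Ibsp and Serping1 fell by 0.77, 0.96 and 0.38, again with the same counts. The calls of Ncr1, Cd34, Tek, Pdgfrb, Adipoq, Ibsp and Serping1 were each lost without AML array 2 (adjusted p 0.0518 to 0.116) and without at least 1 control array (adjusted p 0.0571 to 0.162), namely control array 1 for Cd34, Tek, Pdgfrb and Serping1, control array 2 for these and Ncr1, and control array 3 for each but Cd34. Those of Ncr1, Cd34, Tek, Pdgfrb and Ibsp were also lost without AML array 1 (adjusted p 0.0553 to 0.108), and those of Ncr1 and Serping1 without AML array 3 (adjusted p 0.053 and 0.0672). Under each of the 3 other scalings 0 T and NK cell genes rose and 3 fell, and 0 stromal genes rose and 4 fell. Cd34 lost its call under median centring (adjusted p = 0.0615), which left 0 stem cell rises, and 2 stem cell genes fell without AML array 3. The brightest members, fixed beforehand, were not past the threshold: Cd5 and Cd4 (+0.04 and -0.29), Adgrg1 and Slamf1 (+0.09 and +0.36), and Col1a1 and Col1a2 (+0.13 and +0.12).

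**Figure D2:**
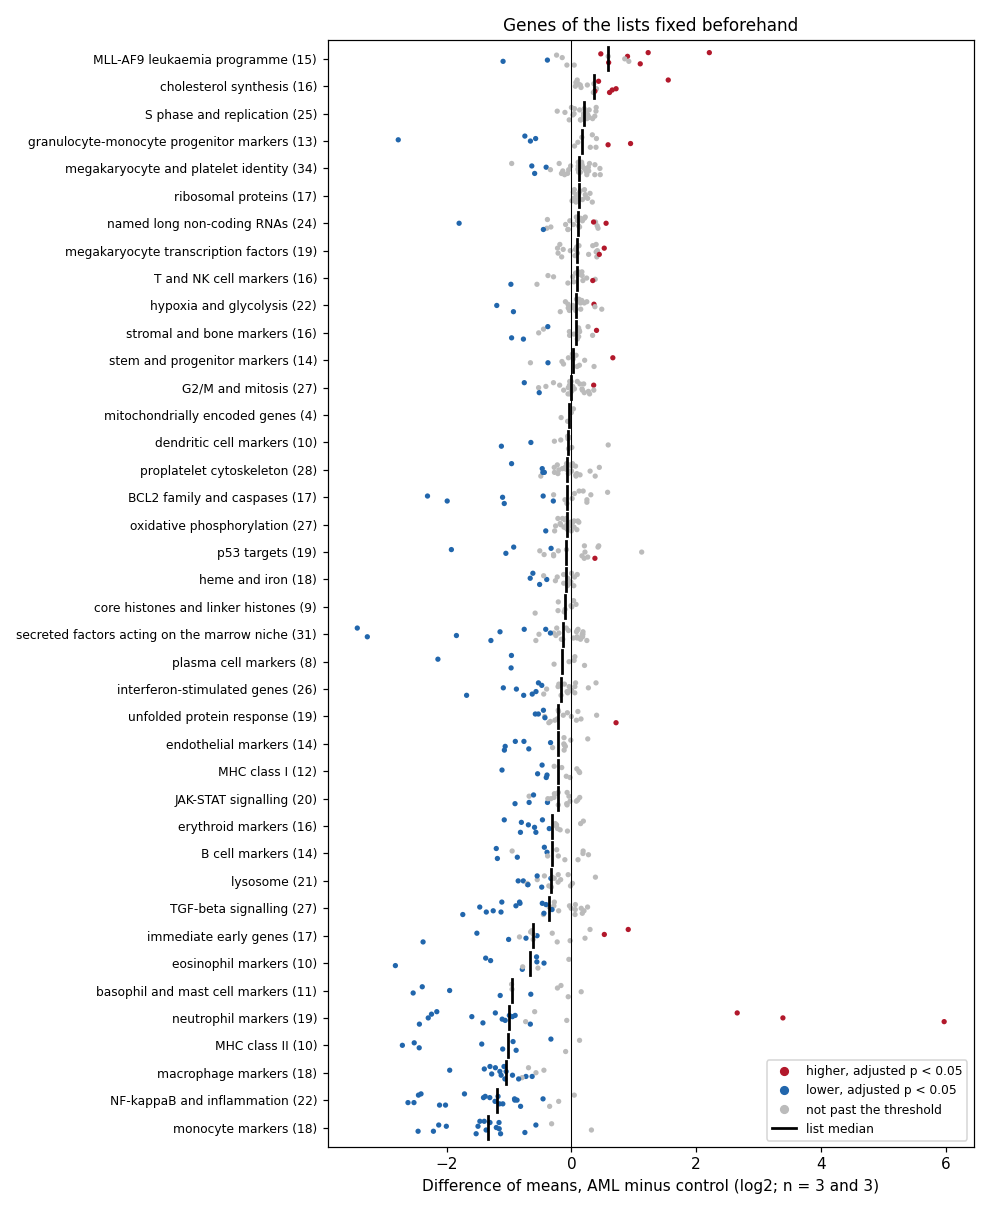
Difference of group means (log2, AML minus control, 3 arrays each) of every measured gene of the 40 gene lists, with blue for lower, red for higher and grey for not past the adjusted threshold, and a bar at each list's median before subtracting the median of all genes. Monocyte, NF-kappaB, macrophage and MHC class II genes lie mostly below 0, and 3 stefins lie far above the other neutrophil markers.

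Inflammatory and antigen presentation genes stood lower as groups. So did the markers of monocytes, macrophages and B cells in the same sorts (relative medians -1.44, -1.16 and -0.42). Which cells the inflammatory and antigen presentation transcripts came from is not known from these data. Of 22 genes of NF-kappaB and inflammation, 19 fell (20 adjusted over the list alone) and 0 rose (adjusted p = 7.5e-24, relative median -1.31, adjusted p = 0.0786 with an estimated correlation). Ptgs2, cyclooxygenase 2, fell 5.33-fold from 9.47 ± 0.07 to 7.06 ± 0.19, Nlrp3, the inflammasome sensor, fell 5.76-fold, and Tnfaip3 and Birc3, both induced by NF-kappaB, fell by 2.02 and 1.41. Of 10 MHC class II genes, 8 fell, also adjusted over the list alone, and 0 rose (adjusted p = 5.4e-12, relative median -1.13, adjusted p = 0.0786 with an estimated correlation). H2-Ab1 fell 5.44-fold from 11.12 ± 0.06 to 8.68 ± 0.11 and H2-Aa 5.74-fold. Of 12 MHC class I genes, 5 fell (6 adjusted over the list alone) and 0 rose (adjusted p = 7.5e-05, relative median -0.32, adjusted p = 0.238 with an estimated correlation). H2-M3 fell by 1.11 and H2-D1 by 0.54, and the count was 3 without AML array 1, 3 without AML array 2, 2 without control array 2 and 2 without control array 3. Of 26 interferon-stimulated genes, 8 fell, also adjusted over the list alone, and 0 rose (adjusted p = 1.5e-06, relative median -0.28, adjusted p = 0.208 with an estimated correlation). Ifih1, a sensor of viral RNA, fell by 1.09, the chemokine gene Cxcl10 by 1.68 and Isg15 by 0.77, the count was 5 without AML array 1, control array 2 or control array 3, and 2 genes rose without AML array 3. Of 17 immediate early genes, 5 fell and 2 rose (9 and 2 adjusted over the list alone; adjusted p = 6.7e-06, relative median -0.72, adjusted p = 0.156 with an estimated correlation). Btg1, an antiproliferative gene, fell 5.20-fold, the phosphatase gene Dusp1 fell by 1.52 and Zfp36 by 1.01, while Myc rose by +0.91 and Egr3 by +0.53. The calls of Myc and Egr3 were lost without control array 2 or 3 (adjusted p 0.0675 to 0.142), and that of Myc also without AML array 1, AML array 2 or control array 1 (adjusted p 0.0838 to 0.113) and under median centring (adjusted p = 0.0840). The falls numbered 3 without control array 2 and 3 without control array 3.

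Cholesterol synthesis was the 1 list that passed upward. Of 16 genes, 6 rose (10 adjusted over the list alone) and 0 fell (adjusted p = 4.2e-04, relative median +0.25, adjusted p = 0.298 with an estimated correlation). Fdps, farnesyl diphosphate synthase, rose 2.93-fold from 7.42 ± 0.02 to 8.98 ± 0.27 (adjusted p = 0.00133), and Sqle, squalene epoxidase, rose by +0.72. The count was 2 without AML array 2, 2 without control array 2 and 3 without control array 3, and 4 under quantile normalization, 2 under median centring and 5 under cyclic loess.

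Survival, stress and organelle genes held smaller groups of lower genes. Of 17 genes of the BCL2 family and caspases, 6 fell and 0 rose, and adjusted over the list alone 6 fell and 4 rose (adjusted p = 0.00451, relative median -0.18, adjusted p = 0.208 with an estimated correlation). Bcl2a1a and Bcl2a1d, close paralogs of a survival factor, fell by 2.31 and 1.99, and Bcl2l11, which encodes the death-promoting BIM, fell by 1.11. Of 21 lysosomal genes, 7 fell and 0 rose (adjusted over the list alone 14 fell and 1 rose; adjusted p = 1.9e-08, relative median -0.44, adjusted p = 0.240 with an estimated correlation). Gla, alpha-galactosidase, fell by 0.77, and the count was 2 without AML array 2, 4 without control array 1, 1 without control array 2 and 1 without control array 3. Of 18 heme and iron genes, 4 fell (5 adjusted over the list alone) and 0 rose, 2 without control array 2 and 2 without control array 3 (adjusted p = 2.5e-04, relative median -0.20, adjusted p = 0.238 with an estimated correlation). Blvrb fell by 0.66 and Ftl1, the ferritin light chain, by 0.51. Of 19 genes of the unfolded protein response, 4 fell and 1 rose, and adjusted over the list alone 6 fell and 2 rose (adjusted p = 3.6e-04, relative median -0.32, adjusted p = 0.244 with an estimated correlation). Herpud1 fell by 0.58 and Asns, asparagine synthetase, rose by +0.71. The falls numbered 1 without AML array 1 and 0 without AML array 2, control array 2 or control array 3, and the call of Asns was lost without AML array 2 (adjusted p = 0.0611) or control array 2 (adjusted p = 0.0638). Of 27 genes of oxidative phosphorylation, 1 fell, and 0 adjusted over the list alone (adjusted p = 0.00207, relative median -0.18, adjusted p = 0.539 with an estimated correlation). This was Sdhb, a subunit of complex II, which fell by 0.41, not without any single array but control array 1 (adjusted p 0.0521 to 0.109).

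Lists of proliferation, ribosomal proteins, histones, hypoxia and p53 targets did not pass. Of 27 G2/M genes, 1 rose and 2 fell, and adjusted over the list alone 2 rose and 3 fell (adjusted p = 0.250, relative median -0.11, and the median itself, -0.004, turned above 0 under quantile normalization). Aurka rose by +0.36, and Kif23 and Nusap1 fell by 0.76 and 0.52, all chosen after their values were seen, as were the members named for hypoxia and p53 targets. Without AML array 3, 3 genes rose. The list passed downward without AML array 1 (adjusted p = 0.0245), and the calls of Aurka and Nusap1 were lost without any single array but AML array 3 (adjusted p 0.0505 to 0.0914). Under median centring Aurka lost its call (adjusted p = 0.134), with 0 rises and 3 falls among G2/M genes. Of 25 S phase genes, 0 passed, also adjusted over the list alone (adjusted p = 0.250, relative median +0.10), and without AML array 3 or control array 3 the list passed upward (adjusted p = 0.0019 and 0.0256), with 5 genes risen without AML array 3. The S phase list also passed upward with array weights, under quantile normalization and cyclic loess (1 gene risen in each of these 2), and with genes below the median level or at the receptor level left out (adjusted p 0.0026 to 0.0267), in all 7 of 18 alternatives. Of 17 ribosomal protein genes, 0 passed, also adjusted over the list alone (adjusted p = 0.136, relative median +0.01), and the list passed upward without AML array 3 (adjusted p = 0.0081, 2 genes risen) or control array 3 (adjusted p = 0.0153). The ribosomal list also passed upward in the same 5 other settings (adjusted p 4.6e-04 to 0.0267), in all 7 of 18 alternatives, with 3 genes risen under quantile normalization and 3 under cyclic loess. Of 9 histone genes, 0 passed, also adjusted over the list alone (adjusted p = 0.0541, relative median -0.21), and the list passed downward without AML array 1 (adjusted p = 0.0170), AML array 3 (adjusted p = 0.0381), with 1 gene fallen in each case, or control array 2 (adjusted p = 0.0318), and under quantile normalization (adjusted p = 0.0163) and cyclic loess (adjusted p = 0.0238, 1 gene fallen). Of 22 genes of hypoxia and glycolysis, Car9 rose by +0.36, Hif1a fell 2.29-fold and Adm fell by 0.93, 2 and 2 without AML array 3, the same as at first when adjusted over the list alone (adjusted p = 0.812, relative median -0.03, and the median itself, +0.07, turned below 0 under median centring while the test pointed down), and 0 rose under each of the 3 other scalings. Of 19 p53 targets, Aen rose by +0.38 and Plk2, Perp, Trp53inp1 and Mdm2 fell by 1.93, 1.05, 0.93 and 0.33, and adjusted over the list alone 3 rose and 5 fell (adjusted p = 0.0803, relative median -0.19). Under median centring 0 p53 targets rose, and the list passed downward with the mean of a gene's rows (adjusted p = 0.0257) and with fry (adjusted p = 0.0134). The calls of Car9, Aen, Trp53inp1 and Mdm2 were lost without control array 2 or 3 (adjusted p 0.0605 to 0.158), all but that of Aen also without AML array 2 (adjusted p 0.0506 to 0.114), all but that of Trp53inp1 without AML array 1 (adjusted p 0.0745 to 0.091), and those of Car9 and Mdm2 without control array 1 (adjusted p 0.087 and 0.0502). That of Mdm2 was lost without AML array 3 (adjusted p = 0.0547) and under quantile normalization (adjusted p = 0.0800) too. The 4 mitochondrially encoded genes measured were too few for the set test, and 0 of them passed, or 1 without AML array 3 (relative median -0.14).

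Long non-coding RNAs chosen beforehand moved both ways. Of 24, 2 rose and 2 fell, and adjusted over the list alone 4 rose and 3 fell. All 4 were chosen after their values were seen. Mir155, the gene of the inflammatory microRNA miR-155, fell 3.49-fold from 7.14 ± 0.38 to 5.34 ± 0.43, and Tug1 fell by 0.45, while the small nucleolar RNA hosts Snhg11 and Snhg5 rose by +0.35 and +0.56. The calls of Tug1, Snhg11 and Snhg5 were lost without AML array 2 or any single control array (adjusted p 0.06 to 0.161), those of Tug1 and Snhg5 also without AML array 1 (adjusted p 0.07 and 0.114) and that of Snhg11 without AML array 3 (adjusted p = 0.0675). The list did not pass (adjusted p = 0.698), and its median (+0.10) and its mean (-0.005) differed in sign. Under quantile normalization 0 rose and 1 fell (the calls of Tug1, Snhg11 and Snhg5 were lost, adjusted p 0.0503 to 0.0722), under median centring 0 and 2, and under cyclic loess 1 and 2. The median turned below 0 under median centring and cyclic loess, and fry pointed up (adjusted p = 0.0040).

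Of the other members named by the rule, the monocyte chemokine gene Ccl6 fell by 1.14, the macrophage factor Maf by 1.28, the eosinophil genes Adora3 and Ear10 by 0.79 and 0.56, the neutrophil granule gene Ngp by 1.11 and the complement gene C1qb by 1.15. The B cell receptor genes Cd79a and Cd79b fell by 0.43 and 0.39, the erythroid genes Car1 and Rhd by 1.08 and 0.59, and the endothelial genes Emcn, Ptprb and Cldn5 by 1.06, 0.68 and 0.76. Parp14 fell by 0.88, Casp1 by 1.08, H2-K1 and B2m by 0.47 and 0.40, H2-DMb1 by 1.44, Bach1 and Fth1 by 0.62 and 0.40, Klf6 by 0.73, the stress response genes Eif2ak3, Atf6 and Atf3 by 0.43, 0.45 and 0.53, and the lysosomal genes Ctsl, Npc1 and Lamp1 by 0.70, 0.70 and 0.48. The cholesterol genes Hsd17b7 and Lss rose by +0.65 and +0.38. Not past the threshold were Mzb1, Flt3, Cd209d, Ndufa1, Ndufs1 and Uqcrc2 (-0.28, -0.27, -0.17, -0.27, -0.17 and -0.22), Prg3 (-0.54) and Cd68 (-0.79, adjusted p = 0.0516). Cd68 passed downward in 7 of 17 alternatives (adjusted p 0.0141 to 0.0484), among them leaving out AML array 1 (adjusted p = 0.0141), and Flt3 in 6 of 15 (adjusted p 0.0151 to 0.0430). Calls were lost without AML array 1 for Cd79a, Eif2ak3, Atf6, Atf3, Lss, B2m and Fth1 (adjusted p 0.0522 to 0.107), and without AML array 2 for these and Emcn, Ptprb, Cldn5, Hsd17b7, Npc1, Lamp1, C1qb and Cd79b (adjusted p 0.0505 to 0.121). They were lost without AML array 3 for Cd79a and Cd79b (adjusted p 0.0596 and 0.0756), and without control array 1 for these and Atf3 (adjusted p 0.0633 to 0.0723). Without control array 3 they were lost for Cldn5, Eif2ak3, Atf6, Atf3, Hsd17b7, Lss, Ctsl, Npc1, Lamp1, H2-K1, B2m, Bach1, Fth1, Klf6, C1qb and Cd79b (adjusted p 0.0514 to 0.156), and without control array 2 for these, Cd79a, Rhd and Ptprb (adjusted p 0.0531 to 0.157). Lss lost its call under each other scaling (adjusted p 0.0712 or more), Hsd17b7 under median centring (adjusted p = 0.0505), Atf3 under quantile normalization and cyclic loess (adjusted p = 0.0741 and 0.0671) and Cd79b under quantile normalization (adjusted p = 0.0639).

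Of the 217 genes tested by name, 38 had 1 group mean and 16 both group means at or below 5.51, the 95th percentile of the means of olfactory and vomeronasal receptor genes, and were not shown to be above background there. For the former a fall is a lower bound, as is a rise far above the shift of the receptor genes themselves (median +0.24). Smaller rises, such as those of Car9 and Hsd17b7, are not called lower bounds, as a shift of background cannot be told apart. Beside the stefins, Ly6k, Cd209a, Slamf7 and Fcer1a, the genes low in 1 group included Mir155, Hoxa6, Jchain, Bcl2a1d, Cxcl10, Cxcl12, Spic, Fcrla, Ebf1, Irf4, Prdm1, Siglech, Stab2, H2-M3, Car1, Emcn, Adm, Car9, Hsd17b7, Tek and Serping1. Low in both groups were Hoxa3, Ncr1, Klrd1, Adipoq, Ibsp, Snhg11, Ms4a1, Ms4a2, Rhag, Isg15, Lss, Ptprb, Mzb1, Flt3 and Cd209d.

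With the preset correlation, 25 of 39 tested lists passed, 24 downward and 1 upward. With an estimated correlation 0 passed, 12 were at an unadjusted p under 0.05 and the lowest adjusted p was 0.0786, and fry, which does not set a list against other genes, called 23. With the preset correlation, the other splits of the 6 arrays into 3 and 3 gave 12 to 24 lists. Lists past the threshold at first were not past it under cyclic loess for proplatelet genes, the BCL2 family and oxidative phosphorylation (adjusted p = 0.103, 0.0964 and 0.226) and under quantile normalization for the BCL2 family (adjusted p = 0.0708). With genes below the median level left out, these 3 and the plasma and dendritic cell markers were not past it (adjusted p 0.116 to 0.138), the plasma cell markers also not with genes below the lower tertile left out (adjusted p = 0.0563), and with genes at the receptor level left out neither were these 5, B cell markers, erythroid markers and the unfolded protein response (adjusted p 0.0530 to 0.235). Quantile normalization and cyclic loess added 1 rise to the secreted factors and to TGF-beta genes and 2 to the BCL2 family. Leaving out 1 array also added 1 rise each to monocyte, lysosomal, p53 and long non-coding RNA genes (AML array 3), to the BCL2 family (AML array 2 or 3), to proplatelet genes (AML array 2) and to megakaryocyte identity genes (control array 1), and 2 new rises to stromal genes (control array 1). Over the single genes tested by name, taking the replicate number as a block ended 60 calls (adjusted p 0.0517 to 0.138) and added 0, while array weights ended 0 and added 8.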

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

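The tests of receptor genes below were chosen only after the result was seen. The control probes of the array are outside the comparison of genes, and the kinds below had a mean on an AML array above that of every control array. The 8 hybridization and labelling controls of AML array 3 lay 0.502 above the highest control array (log2). The 23 background rows of AML array 3 lay 0.173 above it and its 186 unmapped transcripts 0.178. The 155 ERCC spike-in rows lay 0.0828 above it on AML array 3 and 0.0288 above it on AML array 2. Negative and positive control rows had lower means in AML, 4.37 against 4.51 and 7.18 against 7.35.

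Olfactory and vomeronasal receptor genes, a family of 1718 dim genes, had a median difference of +0.24, or +0.13 relative to all genes, and 117 passed upward and 0 downward, while under median centring 69 and 1 passed and under cyclic loess 67 and 3. Without AML array 2 there were 55 rises, without control array 2 there were 21 and without control array 3 there were 22. Over all 6 arrays, genes matched on level had a median of 0.122 (0.109 to 0.137 over 10000 random sets). That range holds the sampling of genes and not the spread between samples. The matching was not repeated without AML array 3, so a shift shared by all dim genes cannot be told apart. An effect of AML array 3, where the hybridization controls stood higher, stays open. Without that array the receptor genes lay 0.0406 above all genes (0.134 against 0.0929), while without any other single array they lay 0.112 to 0.184 above. The 109 rises without AML array 3 were 6.34% of these genes, against 5.45% of all genes. Also open is a change of background that depends on probe sequence, or a low level of these transcripts in leukaemic marrow, neither of which was tested.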

How the results depend on the processing

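Leaving out control rows, counting identical rows once and leaving out genes at the level of receptor genes were chosen only after seeing the data. In none of the settings that refit the genes did a gene called at first change sign. Of the 120 genes named by the rule and past the threshold, 84 kept their call under all of up to 17 alternatives, as did 27 of the 64 named after their values were seen. Tgfb1 stayed short of the threshold under all 17, with differences of 0.0755 to 0.25 (adjusted p 0.113 to 0.695). Over named genes, 3219 results stayed on the same side, 360 lost and 32 gained a call. Over lists, 595 stayed, 47 lost and 27 gained a call. The causes of the changes below were not tested, save where a count follows by construction. No detection calls were used here, so that signal over background is not known gene by gene. The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. The real grouping was the 1 of 10 with as many genes (3230, highest other 1), the 1 of 10 with as many rows (2995, highest other 0) and the 1 of 10 with as many lists (25, highest other 24).

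The replicate number as a block gave 1067 genes (206 higher, 861 lower) and 880 rows. Correlations of deviations between same-numbered arrays were -0.36, 0.14 and -0.29, and 0 of 6 arrays correlated best with the array of its own number. The highest was 0.43, AML array 3 with control array 1. Deviations within a group sum to 0, so these correlations are not independent. They cannot exclude that the numbers pair the samples. Array weights gave 7853 genes (4839 higher, 3014 lower) and 8350 rows. Median centring gave 482 higher genes. A 1.5-fold minimum left 1565 genes (439 higher, 1126 lower), by construction, and an unadjusted p with a 2-fold minimum gave 673 (208 higher, 465 lower), 111 of them not past the adjusted threshold. Without 1 array, genes past the threshold ranged from 967 to 3606 (185 to 1639 higher, 782 to 1967 lower), rows from 568 to 3300 and lists from 25 to 30. The low counts of genes were 967 without control array 2, 1058 without control array 3, 1473 without AML array 2 and 1938 without AML array 1. The count was 3606 without AML array 3 and 2931 without control array 1. Each of these fits lacked 1 array, so the count depended on which array was left out. With an estimated correlation 0 lists passed and 12 were at an unadjusted p under 0.05, while fry called 23.

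Differences of genes that were not called changed sign. Mpo became -0.060 with array weights, -0.060 under median centring and -0.100 to 0.194 without 1 array. Xbp1 became 0.049 with array weights, 0.0093 under cyclic loess and -0.140 to 0.108 without 1 array. Adgrg1 became -0.0037 with array weights and -0.019 under median centring. Cd5 became -0.0058 under quantile normalization, -0.073 under median centring, -0.023 under cyclic loess and -0.0158 to 0.0718 without 1 array, and Itga2b -0.0075 to 0.440 without 1 array.

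For lists that were not called at first, the direction of the test turned while the medians were as follows. Under quantile normalization this was hypoxia (0.0786). Under cyclic loess it was megakaryocyte identity (0.155), progenitors (0.202), hypoxia (0.0611) and long non-coding RNAs (-0.00036). With genes below the lower tertile left out it was T and NK cells (0.136), stroma (0.120) and hypoxia (0.0727). With genes below the median level left out it was megakaryocyte identity (0.121), G2/M (-0.0038), progenitors (0.167), stroma (0.131) and hypoxia (0.0727). With genes at the receptor level left out it was megakaryocyte identity (0.121), progenitors (0.167), stem cells (0.0617), stroma (0.131) and hypoxia (0.0518). With fry it was megakaryocyte identity (0.121), T and NK cells (0.0870), stem cells (0.0307), hypoxia (0.0727) and long non-coding RNAs (0.105). Without 1 array it was megakaryocyte identity (-0.070 to 0.281), transcription factors (0.0838 to 0.20) and hypoxia (0.0520 to 0.112).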

Other observations

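The gene families, the single genes named beside them and the tests of a common fall, of neutrophils and of leukaemic cells were chosen only after the result was seen. Families of myeloid and inflammatory genes, 8 in all, held 57 lower genes in AML, 20 of which are members of the lists as well. Of 11 Clec4 C-type lectin genes, 9 fell, with Clec4b1 at 6.37 ± 0.26 against 8.57 ± 0.07 (n = 3 per group, as in the values below), of 20 Ms4a membrane protein genes 12 fell, with Ms4a4a at 4.93 ± 0.27 against 7.09 ± 0.24, and of 10 interferon-inducible Ifi20x genes 6 fell, with Ifi207 at 7.62 ± 0.47 against 9.85 ± 0.14 and Ifi211 fallen by 2.37. In these families 0 genes rose. Of 34 chemokine ligand genes, 14 fell and 0 rose (1 rose without control array 1), among the fallen the monocyte attractants Ccl2 (fell by 2.42) and Ccl7 (fell by 2.48). Of 30 interleukin genes 7 fell and of 5 Slamf receptor genes 4 fell. All 3 Bcl2a1 paralogs fell. Of 8 granzyme genes 2 fell, Gzmb and Gzmc, the latter from 7.54 ± 0.36 to 5.30 ± 0.13, while the family's median (+0.06) turned below 0 under other scalings. Of 117 immunoglobulin heavy V segments 13 fell and of 86 kappa V segments 7 fell, with 0 rises in either. Over all 302 genes annotated as V segments, 16 rose and 20 fell.

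Non-coding transcripts changed in both directions. Of 955 small nucleolar RNA genes, 90 rose and 9 fell, with a median of +0.32 (+0.22 relative to all genes) that stayed above 0 under each other scaling. The 3006 genes of like level (median 4.61) had a median difference of +0.15. The small nucleolar RNA genes had a median level of 4.64, below 5.51, so many were not shown to be above background. Their rises numbered 17 without AML array 2, 5 without control array 2 and 7 without control array 3, and 156 without control array 1, or 47 under median centring, and their falls 16 without AML array 3, 5 without AML array 2 and 3 without control array 2. Among long non-coding RNAs, 1810006J02Rik rose at least 5.72-fold (its control mean was not shown to be above background) from 4.76 ± 0.13 to 7.28 ± 0.63, AW112010, an inflammation-linked transcript, fell 3.78-fold from 7.82 ± 0.14 to 5.90 ± 0.25, and Mirt2 and Lncpint fell by 1.21 and 1.10. The falls of Ms4a4a, Ccl7, Gzmc and Lncpint are lower bounds too, since their AML means were at or below 5.51, the 95th percentile of receptor gene means. Cd86, the costimulatory receptor gene, fell from 9.46 ± 0.08 to 6.98 ± 0.23.

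Genes of mature myeloid cells and inflammation stood lower in AML, a pattern for which a candidate explanation is a smaller share of other marrow cells among the sorted megakaryocytes, which a gate on side scatter, CD41 and 8N DNA content would remove as single cells but not as aggregates. One common fall of all other blood cells would lower the progenitor and monocyte lists alike. The progenitor list's median lay 1.5 above that of the monocyte list (13 and 18 genes), with Mpo at 10.32 and 10.27. The permutation p of 7.3e-04 came from exchanging genes between the lists, and genes are not independent replicates. It does not measure the spread between samples, and the comparison was chosen after both medians were seen. Shares that changed unequally between cell types were not tested. The monocyte median was -1.27 without AML array 3 and at most -1.31 under the 3 other normalizations. The value without AML array 3 argues against an effect of that array as the whole cause. The 3 other normalizations argue against a shift left between the deposited arrays as the whole cause. They were applied to RMA values, so they cannot test the normalization within RMA. A fixed mixture that loses monocytes cannot be told apart from changes within cells, since the SD over 18 bright monocyte markers, 0.686, lay between the bounds of 0.5 and 1 set before, while the abundant Ly6c2 (12.27 against 11.95) did not follow Lyz2 (9.53 against 11.03). A response of the megakaryocytes themselves to leukaemic marrow stays open as a hypothesis, as does a change in the composition of monocytes, and how many of these markers, of which the lists share 0, megakaryocytes also express was not known from these data.

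The stefin genes of 1 cluster on chromosome 16 (neighbour order from GRCm38.p6) stood higher in AML, 10 of 10 past the threshold with a median of +3.30 and 10 of 10 under each scaling and without each array, Cstdc3 least (+0.93, low in both groups). A larger share of mature neutrophils in the AML sort would raise other neutrophil markers too. The 16 others had a median of -1.09 (range -2.44 to -0.076), with Camp and S100a8 among the lower genes. These falls were already known when the comparison was chosen, so its outcome was not open. A strain difference reaching beyond the cluster cannot be told apart, since 5 of the 20 nearest measured protein-coding genes passed (2.57 expected, one-sided exact hypergeometric p = 0.103), namely Parp14, Cd86, Slc15a2 and Hcls1, which fell, and Fam162a, which rose. The calls of Hcls1 and Fam162a were lost without control array 2 (adjusted p = 0.0986 and 0.0572), and that of Hcls1 also without AML array 2 (adjusted p = 0.075) or control array 3 (adjusted p = 0.0741). Leukaemic cells attached to AML megakaryocytes, or stefin expression by the megakaryocytes themselves, may account for the rise, and the former stays open because the MLL-AF9 programme list had a median of +0.59 against +0.11 over all genes but an adjusted p of 0.257.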
